A study of Mus musculus with 6 samples.

How the data were processed

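RNA abundance was measured in lineage-negative cells of mouse fetal liver at embryonic day 15.5, sorted by flow cytometry to be free of the surface antigens CD3, CD8a, CD19, B220, GR1, CD11b, CD11c and TER119. Such cells are enriched in hematopoietic stem and progenitor cells. There were 3 arrays from wild type embryos and 3 from Geminin-KO embryos, on a mixed strain background. Groups and replicate numbers were taken from the labels, which call the replicates biological.

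Total RNA was isolated with a silica column kit, fragmented and biotinylated with an Affymetrix whole-transcript labelling kit, per the labels' protocols. The values were deposited as a table of 1 linear intensity per probe set and array, for an Affymetrix mouse gene array that probes whole transcripts. The method and software of background correction, normalization and summary, and any offset added, are not given in the sources used here. The deposited intensities ran from 25.87 to 20753.1, and no value lay near 0. Whether a floor or an offset remained in the values is not known, and its size was not estimated. Array medians ran from 227.84 to 241.44. No scanner images or cell files were analysed here, and signal over background was not available per probe set, so the number of arrays was the known limit on precision.

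The deposited intensities were turned into log2 values with no pseudocount. Medians and quartiles of the log2 values differed between arrays by at most 0.0837, under the tolerance of 0.1 fixed beforehand, so no further normalization was applied. The table held 28856 probe sets, of which 21789 had 1 gene symbol in the platform annotation, 1621 had several and 5446 had none there. Of the probe sets with 1 symbol, 21698 had an Entrez identifier in the RefSeq gene table of GRCm38.p6, and this match changed 0 symbols. Genes were named only from probe sets with 1 symbol. For the 999 genes with more than 1 probe set, the brightest probe set over all 6 arrays stood for the gene, which left 19938 genes. The genome build of the array's design was not given, so no coordinates are printed.

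Geminin-KO was compared with wild type by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the genotype as the only term, over all 6 arrays. The fit had 4 residual and 2.4 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The thresholds stated for the study, a fold change over 1.5 with p under 0.05, were counted separately on the unadjusted limma p, since the sources do not say whether that p was adjusted. Error bars are SD over 3 arrays, and SE is the moderated standard error of the log2 fold change.

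There were 27 gene lists with 771 members, of which 687 members were measured, and 16 others lay on probe sets shared by several genes. The lists were written from textbook knowledge. The 4 measured sex-linked genes were only described, and the other 26 lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists. Camera with a correlation estimated per list and fry were run as alternatives. With the estimated correlation, 0 of the 26 lists passed adjusted p of 0.05 and 4 passed at unadjusted p of 0.05, and fry's directional test passed 18. Fry asks whether members move one way on balance and does not compare them with other genes. Of the 645 distinct list genes measured, 38 were in more than 1 list.

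The list tests, the thresholds, the naming rule and the other settings to try were set before the data were examined. The rule named Gmnn, the 12 largest rises and the 12 largest falls past adjusted p of 0.05 with no overlap between the groups' arrays, leaving out clone-type symbols, receptor families of smell and small RNAs. It also named up to 4 members of each list with the largest change past the study's thresholds, or the member with the smallest p where none passed, and a fixed set: Cdt1, Cdkn1a, Hoxa9, Gata1, Gata2, Spi1, Kit, Flt3, Xist and Ddx3y. Cdkn1a lay on a probe set with several genes and Ddx3y was not named in the annotation used, so neither has a value. Genes named outside this rule are said to be so.

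The alternatives were quantile normalization, centring on array medians, 2 filters on dim genes, all probe sets, averaging of probe sets, a trended and robust prior, array weights, the replicate number as a block, and leaving out each array. Other thresholds and an ordinary linear model p were also tried. Subtracting 16 from each intensity before log2, to see how far fold changes depend on an offset of that size, was added after the data had been seen. The fit was tested on simulated data of 19938 genes in 3 against 3 arrays. It recovered 48 of 50 genes changed by 1.5-fold, 48 of 50 changed by 2-fold, 49 of 49 changed by 4-fold and 50 of 50 changed by 8-fold, with 8 unchanged genes among 216 calls. The other 13 calls were among 32 erythroid list genes lowered by 0.5 on the log2 scale in the same simulation. Of those 32, 1 was also changed by 4-fold, and that list alone passed the list test. Genes were simulated independently of each other, so this does not show how the list test behaves on correlated genes. The changed genes were drawn at random from all genes and given normal noise. The shares recovered therefore may not hold for genes that spread more widely between arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.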

Results

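The transcriptomes of lineage-negative fetal liver cells from Geminin-KO and from wild type embryos were compared at E15.5, with 3 arrays per genotype. Geminin, encoded by Gmnn, binds the licensing factor Cdt1 and keeps replication origins from firing again within a cell cycle, and it also binds chromatin and transcription regulators. The study's title places the comparison within the question of how Geminin acts on self-renewal and fate choice of fetal hematopoietic stem cells. Values are log2 of the deposited intensity. Correlations between arrays over all 28856 probe sets were at least 0.9923 within a genotype and at most 0.9907 between genotypes. Over the 19938 genes, the first principal component held 75.4% of the variance and separated the genotypes. Wild type arrays lay at -24.58, -38.88 and -17.26 and Geminin-KO arrays at 29.99, 36.08 and 14.65.

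Gmnn itself was 2.42-fold lower in Geminin-KO cells. Its level was 8.67 ± 0.136 in wild type (8.74, 8.76 and 8.51 per array) and 7.40 ± 0.193 in Geminin-KO (7.37, 7.22 and 7.60; log2, SD, n = 3 each), a log2 fold change of -1.27 (SE 0.115, limma adjusted p = 0.00199). All 3 Geminin-KO arrays lay below all 3 wild type arrays, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Whether the probe set lies within the deleted part of the gene is not given, so the remaining signal does not measure remaining intact transcript. Its partner Cdt1 fell slightly, by 0.28 on the log2 scale (SE 0.057, adjusted p = 0.0221), though it did not pass without wild type replicate 1 or 2 or Geminin-KO replicate 1 or 2 (adjusted p = 0.0669 to 0.0757).

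Across 19938 genes, 1996 rose and 1198 fell in Geminin-KO cells at adjusted p of 0.05, together 3194. At the thresholds stated for the study, 1327 genes rose and 437 fell, together 1764. The other 9 splits of the 6 arrays gave a median of 0 genes by the first criterion and 23 by the second, and a median of 356 at unadjusted p of 0.05, against 6174 for the real split. For gene lists at the preset correlation, the other splits gave 4 to 21 called lists against 21 for the real one. Each other split mixes the genotypes, so it keeps part of the genotype difference and puts the rest within its groups. Such counts are not a chance expectation. Quantile normalization changed the division of the first count to 1898 up and 1792 down, and centring on array medians to 1846 up and 1462 down. The count of 3194 became 1807 without wild type replicate 1, 1829 without wild type replicate 2, 1535 without Geminin-KO replicate 1 and 1876 without Geminin-KO replicate 2.

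The largest rises joined mast cell proteases, interferon-induced genes and regulators of stem cells. Mcpt4, a mast cell chymase, rose 11.2-fold (log2 fold change 3.48, SE 0.266, adjusted p = 0.00133), and the related protease Mcpt2 rose 6.61-fold. Both were dim in wild type, at 6.52 and 5.70, and their signal over background was not checked. Emcn, which encodes a sialomucin of endothelium and hematopoietic stem cells, rose 8.14-fold from 7.46 ± 0.563 to 10.48 ± 0.085 (log2 fold change 3.03, SE 0.263, adjusted p = 0.0019). Rtp4, an interferon-induced gene, rose 8.03-fold (log2 fold change 3.00, SE 0.29). Lgals3bp rose 6.99-fold and Oasl2 6.24-fold. The other rises among the 12 were 6.77-fold for Ltf, 6.65-fold for Mycn, 6.30-fold for Hlf, 6.25-fold for Mecom, 6.20-fold for Eya1 and 6.16-fold for Gcnt2. Mecom had a second, dimmer probe set with a log2 fold change of 0.90 against 2.64 for the brighter one. Ltf, the neutrophil granule protein lactoferrin, did not pass without wild type replicate 1 or 2 or Geminin-KO replicate 1 or 2 (adjusted p = 0.0671 to 0.0794).

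The largest fall was that of Aqp1, the water channel of red blood cells, 8.03-fold from 11.49 ± 0.126 to 8.48 ± 0.281 (log2, SD, n = 3; log2 fold change -3.00, SE 0.147, adjusted p = 0.000689). Prss50, a serine protease gene, was 5.88-fold lower, Ddah1, whose product breaks down methylated arginine, 5.72-fold, and Gpc4, a glypican, 5.66-fold. Mc2r, the corticotropin receptor, was 4.91-fold lower, and Gjb2, a gap junction protein, 4.90-fold. Muc6, a mucin, was 4.61-fold lower, with adjusted p = 0.0508 without Geminin-KO replicate 1. Sh2d4a was 4.57-fold lower, the sulfate transporter gene Slc26a1 4.24-fold, the sphingosine kinase gene Sphk1 3.99-fold, the mitochondrial carrier gene Slc25a21 3.57-fold and C1qtnf12 3.47-fold. The naming rule chose these 24 genes from those without overlap between the groups' arrays.

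**Figure D1:**
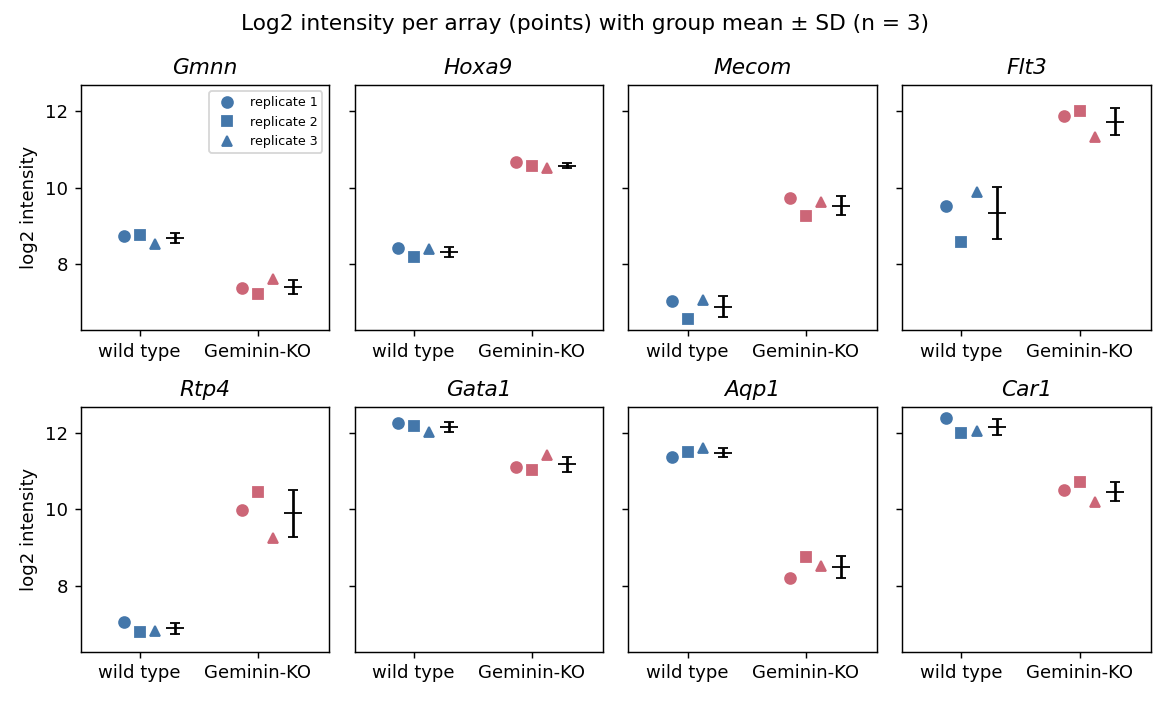
Log2 intensity of 8 genes in each of the 6 arrays, with 3 wild type arrays (blue) and 3 Geminin-KO arrays (red) per panel, marker shapes giving the replicate number and black bars the mean ± SD. Gmnn, Gata1, Aqp1 and Car1 were lower and Hoxa9, Mecom, Flt3 and Rtp4 higher in all 3 Geminin-KO arrays, with Aqp1 falling from a mean of 11.49 to 8.48.

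Genes of hematopoietic stem cells were higher in Geminin-KO cells as a group. Mycn rose from 8.63 ± 0.473 to 11.36 ± 0.09 (log2, SD, n = 3; log2 fold change 2.73, SE 0.224). The stem cell transcription factor genes Hlf (log2 fold change 2.66, SE 0.168), Mecom (2.64, SE 0.175) and Hoxa9 (2.26, SE 0.08) rose with it, at adjusted p between 0.000459 and 0.00155. Of 30 measured stem cell genes, 22 rose and 1 fell, and 24 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 0.98 (camera, adjusted p = 2.96e-17, and adjusted p = 0.18 with an estimated correlation). The member that fell was Mllt3 (log2 fold change -0.39), named after its value was seen. The list mean lay 1.07, 1.03 and 1.03 above the wild type mean in the 3 Geminin-KO arrays. Kit, the stem cell factor receptor, showed no detectable change (log2 fold change 0.04, SE 0.11, adjusted p = 0.82). In the same arrays, the lymphoid and B cell list had a median of 0.86, the T and NK cell list 0.66 and the monocyte and macrophage list 0.02.

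Among Hox genes and their cofactors, 7 of the 10 that rose were Hoxa genes. Hoxa9 rose 4.77-fold from 8.32 ± 0.13 to 10.58 ± 0.077 (log2, SD, n = 3), its cofactor Meis1 3.47-fold (log2 fold change 1.80, SE 0.087), Hoxa6 2.96-fold (1.57, SE 0.123) and Hoxa5 2.71-fold (1.44, SE 0.155). Of 26 measured members, 10 rose and 0 fell, the same counts as when adjusted over the list alone. Camera gave adjusted p = 1.23e-05, and adjusted p = 0.296 with an estimated correlation. The median was 0.06 and the mean 0.41, and 16 members were not called.

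Transcription factor genes of blood lineages went both ways. Erg, an ETS factor of stem cells, rose 4.23-fold (log2 fold change 2.08, SE 0.295, adjusted p = 0.00668), and Gata2, a factor of stem and mast cells, rose 1.80-fold (0.85, SE 0.081, adjusted p = 0.00236). Gata1, which drives erythroid and megakaryocytic differentiation, fell by 0.97 on the log2 scale, from 12.16 ± 0.13 to 11.18 ± 0.198 (SD, n = 3; SE 0.116, adjusted p = 0.00407). Id2 had a log2 fold change of 1.79 (SE 0.52, adjusted p = 0.0663) and Spi1, the myeloid and lymphoid factor PU.1, 1.01 (SE 0.305, adjusted p = 0.0735). Both passed without wild type replicate 2, at smaller log2 fold changes of 1.17 and 0.65 (adjusted p = 0.0307 and 0.0355). They also passed without wild type replicate 3, at 2.23 and 1.26 (adjusted p = 0.0327 and 0.0405). Of 40 measured members, 14 rose and 6 fell, and 19 rose and 6 fell when adjusted over the list alone. The median was 0.47 (camera, adjusted p = 3.21e-05, and adjusted p = 0.326 with an estimated correlation). Without Geminin-KO replicate 1 or 2, 9 rose and 3 fell. The number that fell was also 3 without wild type replicate 2, and the median was 0.31 without Geminin-KO replicate 2.

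Erythroid genes fell. Besides Aqp1, Car1, an erythroid carbonic anhydrase, fell 3.23-fold from 12.16 ± 0.212 to 10.47 ± 0.257 (log2, SD, n = 3; log2 fold change -1.69, SE 0.158, adjusted p = 0.00219). C1qtnf12 had a log2 fold change of -1.80 (SE 0.118), Ermap, an erythroblast membrane protein gene, -1.32 (SE 0.164), and Epor, the erythropoietin receptor gene, -1.32 (SE 0.195). Of 32 measured erythroid genes, 18 fell and 0 rose, and 20 fell and 1 rose when adjusted over the list alone. The median was -0.75 (camera, adjusted p = 5.59e-09, and adjusted p = 0.311 with an estimated correlation). Genes of heme synthesis and iron uptake followed, with 14 of 20 lower and 0 higher, the same counts as when adjusted over the list alone. Their median was -0.69 (camera, adjusted p = 3.42e-07, and adjusted p = 0.311 with an estimated correlation). Among them were the iron transporter gene Slc11a2 (log2 fold change -1.17, SE 0.141), the ferrireductase gene Steap3 (-1.06, SE 0.109), Abcb6 (-1.03, SE 0.144) and the heme synthesis enzyme gene Uros (-0.88, SE 0.113). Adult globin genes lay on probe sets shared by several genes and have no value here. Beside these falls, stem cell genes had a median of 0.98 and monocyte and macrophage genes one of 0.02 in the same arrays.

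Several megakaryocyte and platelet genes were higher in Geminin-KO cells. Mmrn1, a platelet and endothelial protein gene, rose 2.99-fold (log2 fold change 1.58, SE 0.154, adjusted p = 0.00244), Fli1 2.24-fold (1.17, SE 0.228, adjusted p = 0.0194) and the tetraspanin gene Cd9 2.01-fold (1.00, SE 0.15). Ltbp1, which binds latent TGF-beta, fell by 1.53 on the log2 scale (SE 0.138, adjusted p = 0.00199). Of 21 measured members, 7 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone. The median was 0.39 (camera, adjusted p = 1.64e-05, and adjusted p = 0.326 with an estimated correlation). Without Geminin-KO replicate 1, 4 rose, and without Geminin-KO replicate 2, 3 rose. Fli1 did not pass without either (adjusted p = 0.0773 and 0.0662).

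**Figure D2:**
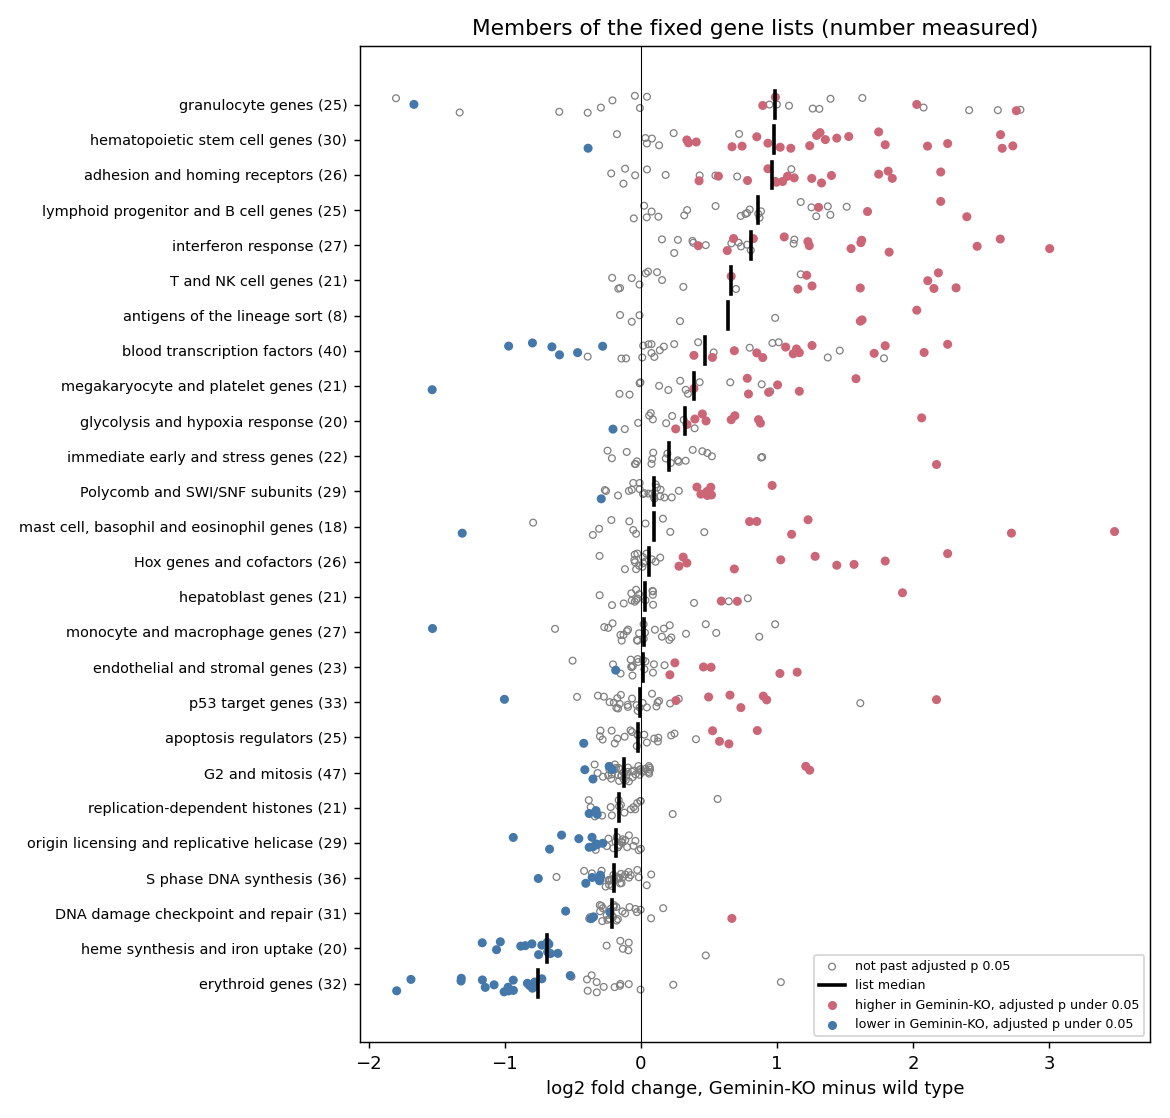
Log2 fold change (Geminin-KO minus wild type, horizontal axis) of each measured member of the 26 tested gene lists, with filled points for members past adjusted p of 0.05 (red higher, blue lower), open points for the others, and black bars for list medians. Medians ran from -0.75 for erythroid genes to 0.99 for granulocyte genes.

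Granulocyte genes were spread widely between arrays and went both ways. The largest values in the list were those of late neutrophil granule genes: Ngp had a log2 fold change of 2.79 (SE 0.77, adjusted p = 0.0573), Lcn2 2.62 (SE 0.865, adjusted p = 0.0929) and Mmp8 2.41 (SE 0.694, adjusted p = 0.0642), none of them called, while Ltf rose (2.76, SE 0.583, adjusted p = 0.025). Of 25 measured members, 4 rose (Ltf, Ly6g, Csf3r and Gfi1) and 1 fell (Ms4a3, log2 fold change -1.67), and 10 rose and 3 fell when adjusted over the list alone. Csf3r, Gfi1 and Ms4a3 were named after their values were seen. The median was 0.99 (camera, adjusted p = 0.00637, and adjusted p = 0.588 with an estimated correlation). The list mean, relative to the wild type mean, was 0.26, -0.64 and 0.39 in the wild type arrays and 1.39, 0.85 and 0.03 in the Geminin-KO arrays. In turn, 0 members rose without wild type replicate 1 or Geminin-KO replicate 1 or 2, 1 without wild type replicate 2 and 8 without Geminin-KO replicate 3. The number that fell was 2 without wild type replicate 2, 0 without any other single array and 0 with the trended and robust prior. The list was not called without wild type replicate 2 (median 0.65, adjusted p = 0.115) or Geminin-KO replicate 1 (median 0.67, adjusted p = 0.0598), with genes under the median of brightness left out (adjusted p = 0.157) or by fry (adjusted p = 0.37). Lcn2 and Mmp8 passed without Geminin-KO replicate 3 (adjusted p = 0.032 and 0.00384), and Ngp without wild type replicate 3 (adjusted p = 0.0397).

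Antigens against which the cells had been sorted were measured as transcripts too. Ly6g, a target of GR1 antibodies, rose 4.08-fold from 6.70 ± 0.171 to 8.73 ± 1.06 (log2, SD, n = 3; log2 fold change 2.03, SE 0.49, adjusted p = 0.0383), Ptprc, the leukocyte antigen gene of which B220 is an isoform, 3.09-fold (1.63, SE 0.281, adjusted p = 0.0131) and Cd3g 3.06-fold (1.61, SE 0.315, adjusted p = 0.0194). Itgam, which encodes CD11b, had a log2 fold change of 0.99 (SE 0.324, adjusted p = 0.0918), with adjusted p = 0.018 without Geminin-KO replicate 3. Of 8 measured antigen genes, 3 rose and 0 fell, and 4 rose when adjusted over the list alone. The median was 0.64 (camera, adjusted p = 0.0307, and adjusted p = 0.35 with an estimated correlation). The list was not called without wild type replicate 1 (adjusted p = 0.0804), Geminin-KO replicate 1 (adjusted p = 0.0534) or Geminin-KO replicate 2 (adjusted p = 0.0509), and the number that rose was 0, 0 and 2. It was also not called by fry (adjusted p = 0.0631) or with genes under the median of brightness left out (adjusted p = 0.0589, 2 members). The number was 1 without wild type replicate 2 and 5 without Geminin-KO replicate 3. With 1 array left out, Ly6g passed only without Geminin-KO replicate 3 (other adjusted p = 0.0699 to 0.116), Ptprc not without wild type replicate 1 or Geminin-KO replicate 1 (adjusted p = 0.0501 and 0.0588), and Cd3g not without those or wild type replicate 2 (adjusted p = 0.0567 to 0.0785).

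Of the lymphoid progenitor and B cell genes, 4 rose and 21 were not called. Flt3, the receptor of multipotent and lymphoid progenitors, rose 5.26-fold from 9.33 ± 0.679 to 11.73 ± 0.362 (log2, SD, n = 3; log2 fold change 2.40, SE 0.354, adjusted p = 0.00775), and Ccr9, a thymus homing receptor, 4.61-fold (2.20, SE 0.178). The chromatin organizer gene Satb1 (1.67, SE 0.297, adjusted p = 0.0144) and Mef2c (1.31, SE 0.156) rose as well. Of 25 measured members, 4 rose and 0 fell, the same counts as when adjusted over the list alone. The median was 0.86 (camera, adjusted p = 3.91e-05, adjusted p = 0.399 with an estimated correlation, and adjusted p = 0.126 by fry). The list mean was 0.84, 1.82 and 0.06 in Geminin-KO replicates 1, 2 and 3, against 0.54 in wild type replicate 3. The median was 0.16 without Geminin-KO replicate 2, 0.56 without wild type replicate 2 and 1.54 without Geminin-KO replicate 3, and Satb1 did not pass without Geminin-KO replicate 1 (adjusted p = 0.0624).

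Several genes of T and NK cells rose, among them cytotoxic granule genes. Gzma had a log2 fold change of 2.32 (SE 0.578, adjusted p = 0.0424), the lymphoid antigen gene Cd7 2.19 (SE 0.391, adjusted p = 0.0145), Gzmb 2.15 (SE 0.539, adjusted p = 0.0428) and Il2rb, an interleukin receptor chain, 2.11 (SE 0.309, adjusted p = 0.00754). Of 21 measured members, 9 rose and 0 fell, and 11 rose when adjusted over the list alone. The median was 0.66 (camera, adjusted p = 8.04e-05, and adjusted p = 0.326 with an estimated correlation). Without wild type replicate 1, wild type replicate 2 or Geminin-KO replicate 1, 3, 4 and 3 members rose, and Gzma (adjusted p = 0.104 to 0.128), Gzmb (adjusted p = 0.0937 to 0.124) and Cd7 (adjusted p = 0.0506 to 0.061) did not pass. Gzmb also did not pass without wild type replicate 3 (adjusted p = 0.0744).

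Mast cell genes went both ways, and 11 of 18 were not called. The protease genes Mcpt4, Mcpt2 and Mcpt1 rose (log2 fold changes 3.48, 2.72 and 1.23), whereas Ms4a2, a chain of the high-affinity IgE receptor, fell by 1.31 (SE 0.292, adjusted p = 0.0295). Gata2 rose by 0.85. Among genes named after their values were seen, Tpsb2 rose by 1.11 (adjusted p = 0.0239) and Cma1 by 0.80 (adjusted p = 0.0078), while Cpa3 (0.47, adjusted p = 0.329), Mcpt8 (-0.79, adjusted p = 0.2), Prss34 (-0.06, adjusted p = 0.815) and Tpsab1 (0.16, adjusted p = 0.0661) were not called. Of 18 measured mast cell, basophil and eosinophil genes, 6 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.0101, and adjusted p = 0.35 with an estimated correlation). Without wild type replicate 2 the list was not called (adjusted p = 0.0763), nor with genes under the lower quartile (adjusted p = 0.0832, 13 members) or under the median of brightness (adjusted p = 0.0953, 7 members) left out. Mcpt1 did not pass without any of the 3 wild type replicates or Geminin-KO replicate 1 (adjusted p = 0.0642 to 0.103), and with 1 array left out Ms4a2 passed only without Geminin-KO replicate 2 (other adjusted p = 0.0516 to 0.0863). The protease genes were dim in wild type, at 6.52, 5.70 and 5.77. Near-identical relatives exist among these proteases, so the probe sets may not tell all of them apart. Monocyte and macrophage genes showed no common direction: 0 of 27 rose and 1 fell, both counts being the same when adjusted over the list alone (median 0.02, and -0.02 with arrays centred on their medians; camera, adjusted p = 0.498). That 1 was Slc40a1, the iron exporter of macrophages and erythroid cells (log2 fold change -1.53, SE 0.128, adjusted p = 0.00163).

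**Figure D3:**
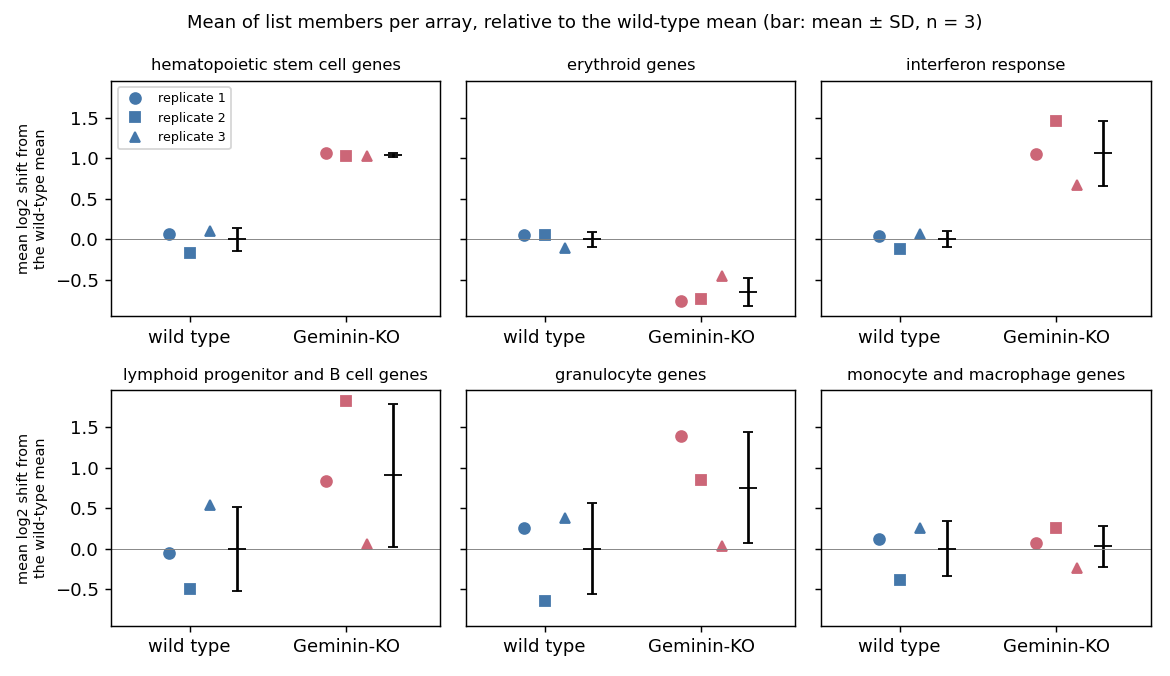
Mean log2 level of the measured members of 6 gene lists in each array, relative to the mean of the 3 wild type arrays, with marker shapes giving the replicate number and black bars the group mean ± SD (n = 3). Stem cell genes lay between 1.03 and 1.07 in the Geminin-KO arrays, while lymphoid genes lay between 0.06 and 1.82.

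Interferon response genes rose. Besides Rtp4 (log2 fold change 3.00) and Oasl2 (2.64, SE 0.384, adjusted p = 0.00735), Ddx58, which encodes the viral RNA sensor RIG-I, rose 5.55-fold from 8.08 ± 0.318 to 10.55 ± 0.386 (log2, SD, n = 3; log2 fold change 2.47, SE 0.232, adjusted p = 0.00222), and Xaf1 rose 3.54-fold. Of 27 measured members, 14 rose and 0 fell, and 23 rose when adjusted over the list alone. All 27 had positive log2 fold changes, with a median of 0.81 (camera, adjusted p = 1.26e-13, and adjusted p = 0.316 with an estimated correlation). The list mean lay 1.06, 1.47 and 0.67 above the wild type mean in the 3 Geminin-KO arrays. The number that rose was 9 without wild type replicate 1 or 2, 8 without Geminin-KO replicate 1 and 22 without Geminin-KO replicate 3. Beside this rise, T and NK cell genes had list means of 0.78, 1.14 and 0.46 in the same 3 arrays.

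Adhesion and homing receptor genes rose, among them Ccr9 (log2 fold change 2.20), Cd48 (1.85, SE 0.272, adjusted p = 0.00763), Cd93 (1.82, SE 0.371, adjusted p = 0.0225) and the junction protein gene Esam, 3.36-fold from 7.84 ± 0.109 to 9.59 ± 0.025 (log2, SD, n = 3; adjusted p = 0.000459). Of 26 measured members, 15 rose and 0 fell, and 18 rose when adjusted over the list alone. The median was 0.96 (camera, adjusted p = 9.77e-11, and adjusted p = 0.299 with an estimated correlation). Without Geminin-KO replicate 1, 9 rose, and Cd93 did not pass without that array, wild type replicate 1 or Geminin-KO replicate 2 (adjusted p = 0.0638 to 0.0816). The list mean lay 0.86, 0.96 and 0.72 above the wild type mean in the 3 Geminin-KO arrays. In the same arrays the T and NK cell list had means of 0.78, 1.14 and 0.46 and the stem cell list 1.07, 1.03 and 1.03, and Ptprc rose by 1.63. The list shares leukocyte genes such as Ccr9 and Itgam with other lists. Genes of glycolysis and the hypoxia response also rose. The prolyl hydroxylase gene Egln3 rose 4.18-fold (log2 fold change 2.06, SE 0.269, adjusted p = 0.00512), the pyruvate kinase gene Pkm 1.84-fold (0.88, SE 0.079, adjusted p = 0.00196), the phosphofructokinase gene Pfkp 1.82-fold and Bnip3 1.61-fold. Of 20 measured members, 10 rose and 1 fell, the same counts as when adjusted over the list alone. The median was 0.33 (camera, adjusted p = 1.05e-06, and adjusted p = 0.18 with an estimated correlation). The member that fell was Pdk1 (log2 fold change -0.20), named after its value was seen, and 0 members fell without any one array other than wild type replicate 3.

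Replication genes were slightly lower in Geminin-KO cells as lists, while most members were not called. Among origin licensing and helicase genes, Orc5, a subunit of the origin recognition complex, fell 1.92-fold from 11.49 ± 0.066 to 10.55 ± 0.215 (log2, SD, n = 3; log2 fold change -0.94, SE 0.111, adjusted p = 0.00402), and the helicase gene Recql4 fell 1.59-fold (-0.67, SE 0.132, adjusted p = 0.0199). Of 29 measured licensing genes, 0 rose and 10 fell, and 12 fell when adjusted over the list alone. The median was -0.19 (camera, adjusted p = 1.23e-05, and adjusted p = 0.326 with an estimated correlation). Ccne1, the cyclin that starts S phase, fell 1.69-fold (log2 fold change -0.75, SE 0.156, adjusted p = 0.0236), and Dscc1 had a log2 fold change of -0.62 (SE 0.178, adjusted p = 0.0635). Of 36 S phase genes, 0 rose and 6 fell, and 11 fell when adjusted over the list alone. The median was -0.20 (camera, adjusted p = 1.64e-05, and adjusted p = 0.311 with an estimated correlation). Without wild type replicate 1, wild type replicate 2, Geminin-KO replicate 1 and Geminin-KO replicate 2 in turn, 1, 2, 1 and 2 licensing genes and 1, 0, 2 and 0 S phase genes fell. Neither Recql4 (adjusted p = 0.0502 to 0.0739) nor Ccne1 (adjusted p = 0.0706 to 0.0874) passed without those arrays. Licensing list means were -0.269, -0.319 and -0.175 in the Geminin-KO arrays, where erythroid list means were -0.753, -0.735 and -0.455. The falls of these lists were not tested apart.

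Mitotic genes showed small falls and a pair of rises. Pimreg (log2 fold change 1.24, SE 0.257, adjusted p = 0.0235) and Cep55 (1.21, SE 0.197, adjusted p = 0.0107), a protein of the final cut between daughter cells, rose. Of 47 measured G2 and mitosis genes, 2 rose and 4 fell (Ccna2, Hmmr, Ttk and Sgo1, named after their values were seen), and 2 rose and 2 fell when adjusted over the list alone. The median was -0.13 (camera, adjusted p = 0.0151, and adjusted p = 0.311 with an estimated correlation). Under quantile normalization the list was not called (adjusted p = 0.28), nor without wild type replicate 3 (adjusted p = 0.0557). None of the 4 was called without wild type replicate 1 or 2 or Geminin-KO replicate 1 or 2, while 8 fell without Geminin-KO replicate 3. Pimreg did not pass without wild type replicate 1 or Geminin-KO replicate 1 or 2 (adjusted p = 0.0577 to 0.0898), nor Cep55 without Geminin-KO replicate 1 (adjusted p = 0.0509). Of 21 measured replication-dependent histone genes, whose near-identical copies make single values uncertain, 0 rose and 3 fell (H2ac4, and H1f1 and H4c3 named after their values were seen), and 4 fell when adjusted over the list alone. H2ac4 had a log2 fold change of -0.32 (SE 0.052, adjusted p = 0.0102). The histone median was -0.16 (camera, adjusted p = 0.0116, and adjusted p = 0.399 with an estimated correlation). That list was not called under quantile normalization (adjusted p = 0.0882) or without wild type replicate 3 (adjusted p = 0.138) or Geminin-KO replicate 3 (adjusted p = 0.0643), and 1 gene fell without Geminin-KO replicate 1.

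Most genes of the DNA damage response and of cell death were not called. Calls were made for 5 of 31 checkpoint and repair genes, 8 of 33 p53 targets and 5 of 25 apoptosis regulators. Among all genes 16% were called, so these counts do not show a lack of response in these lists. Checkpoint and repair genes leaned downward, with positive log2 fold changes in 3 of 31, while p53 targets and apoptosis regulators went both ways. Of 31 measured checkpoint and repair genes, 1 rose (Trp53bp1, log2 fold change 0.67, SE 0.068, adjusted p = 0.00282) and 4 fell (Rad17, Bard1, Tipin and Brca1, named after their values were seen), and 1 rose and 5 fell when adjusted over the list alone. The median was -0.21 (camera, adjusted p = 0.00128, and adjusted p = 0.35 with an estimated correlation). The number that fell was 1 without wild type replicate 1 or 2 or Geminin-KO replicate 1 or 2, and 7 without wild type replicate 3 or under quantile normalization. Among p53 target genes, the kinase gene Plk2 rose 4.51-fold (log2 fold change 2.17, SE 0.457, adjusted p = 0.0248) and Sesn1 1.90-fold (0.93, SE 0.101), while Sesn2, a stress-induced relative, fell by 1.00 (SE 0.138, adjusted p = 0.00601). Trp53inp1 had a log2 fold change of 1.61 (SE 0.511, adjusted p = 0.0837), with adjusted p = 0.0202 without Geminin-KO replicate 3. Of 33 measured targets, 7 rose and 1 fell, 9 rose and 4 fell when adjusted over the list alone, and 6 rose and 5 fell under quantile normalization. The median of -0.01 and the mean of 0.15 differed in sign (camera, upward, adjusted p = 0.252). The number that rose was 3 without wild type replicate 1 or 2 and 4 without Geminin-KO replicate 1, and 6 fell without wild type replicate 3. Plk2 did not pass without wild type replicate 1 or 2 or Geminin-KO replicate 1 or 2 (adjusted p = 0.0762 to 0.0857). Of 25 apoptosis regulators, 4 rose (Bcl2, Casp8, Birc3 and Cflar) and 1 fell (Diablo), and 4 rose and 2 fell when adjusted over the list alone. Casp8, Birc3 and Diablo were named after their values were seen. Bcl2, which protects from apoptosis, rose 1.81-fold (log2 fold change 0.86, SE 0.173, adjusted p = 0.0219), and Cflar, an inhibitor of caspase activation, rose 1.57-fold (0.65, SE 0.126, adjusted p = 0.0193). The apoptosis median of -0.02 and the mean of 0.07 differed in sign (camera, upward, adjusted p = 0.39), and under quantile normalization the median was 0.01, with 4 that rose and 5 that fell. With arrays centred on their medians, 4 rose and 2 fell. Without wild type replicate 1, Geminin-KO replicate 1 or Geminin-KO replicate 2, 1 apoptosis regulator rose, and neither Bcl2 (adjusted p = 0.0593 to 0.0747) nor Cflar (adjusted p = 0.06 to 0.079) passed. The number of apoptosis regulators that fell was 0 without wild type replicate 2 or Geminin-KO replicate 1. It was 3 without wild type replicate 3 and 2 without Geminin-KO replicate 2.

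Among chromatin regulators, Smarca2, an ATPase of SWI/SNF complexes, rose 1.95-fold (log2 fold change 0.96, SE 0.118, adjusted p = 0.00442). Of 29 measured Polycomb and SWI/SNF genes, 7 rose and 1 fell (Ring1, named after its value was seen), the same counts as when adjusted over the list alone. The median was 0.10 (camera, adjusted p = 0.00197, and adjusted p = 0.276 with an estimated correlation). With genes under the median of brightness left out the list was not called (adjusted p = 0.05, 27 members). The number that rose was 2 without wild type replicate 2, 3 without Geminin-KO replicate 1 and 4 without Geminin-KO replicate 2. The number that fell was 0 without wild type replicate 2 or Geminin-KO replicate 2. The immediate early gene Nr4a1, a nuclear receptor, had a log2 fold change of 2.17 (SE 0.534, adjusted p = 0.0407), and Klf6 0.88 (SE 0.318, adjusted p = 0.116). Of 22 measured immediate early and stress genes, 1 rose and 0 fell, and 0 passed when adjusted over the list alone. Camera gave adjusted p = 0.0297, and adjusted p = 0.588 with an estimated correlation. That list was not called under quantile normalization (adjusted p = 0.084) or without wild type replicate 1 (adjusted p = 0.241), Geminin-KO replicate 1 (adjusted p = 0.289) or Geminin-KO replicate 2 (adjusted p = 0.0976). Nor was it called with genes under the lower quartile (adjusted p = 0.0685) or the median of brightness (adjusted p = 0.0627) left out, or by fry (adjusted p = 0.486). Nr4a1 did not pass without those 3 arrays or wild type replicate 2 (adjusted p = 0.118 to 0.125), while 6 members rose and Klf6 had adjusted p = 0.025 without Geminin-KO replicate 3.

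Among genes of other fetal liver cells, 3 of 21 hepatoblast genes and 7 of 23 endothelial and stromal genes were called. Hnf4a, a transcription factor of hepatocytes, rose 3.79-fold from 8.70 ± 0.237 to 10.62 ± 0.09 (log2, SD, n = 3; log2 fold change 1.92, SE 0.123, adjusted p = 0.000976). Dlk1, a hepatoblast surface protein gene, rose 1.63-fold (0.71, SE 0.118) and the keratin gene Krt18 1.51-fold (0.59, SE 0.078), and Trf, which encodes transferrin, had a log2 fold change of 0.79 (SE 0.322, adjusted p = 0.157). These 3 were the members that rose among 21 measured hepatoblast genes, and 0 fell, the same counts as when adjusted over the list alone. Camera gave adjusted p = 0.121, with adjusted p = 0.00643 without wild type replicate 1 and adjusted p = 0.0274 without Geminin-KO replicate 3, and adjusted p = 0.0161 with genes under the median of brightness left out. Of 23 endothelial and stromal genes, 6 rose and 1 fell (Des, named after its value was seen), and 6 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.135, and adjusted p = 0.0375 by fry). Egfl7, an endothelial protein gene, rose 2.22-fold (log2 fold change 1.15, SE 0.057, adjusted p = 0.000689), and Pdgfrb, a stromal receptor, 2.03-fold (1.02, SE 0.176, adjusted p = 0.013). Under quantile normalization 4 of these genes rose and 4 fell, and with arrays centred on their medians 4 rose and 2 fell. There were 3 endothelial and stromal genes that rose without wild type replicate 2 or Geminin-KO replicate 1. The number that fell was 0 without wild type replicate 1 or 2 or Geminin-KO replicate 1 or 2.

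Sex-linked transcripts differed between arrays of the same genotype. Xist, expressed from the inactive X chromosome of females, was at 11.36, 12.69 and 12.79 in the wild type arrays and at 12.20, 6.93 and 12.41 in Geminin-KO replicates 1, 2 and 3 (log2). Kdm5d, on the Y chromosome, was at 9.01, 8.19 and 8.41 in wild type and 9.23, 9.87 and 9.19 in Geminin-KO (log2 fold change 0.90, SE 0.263, adjusted p = 0.0682), with adjusted p = 0.0452 without wild type replicate 1. None of the 4 measured sex-linked genes was called, and 0 passed when adjusted over the list alone.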

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

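The tests of explanations in this part were chosen after the results were seen, while the counts over other splits of the arrays were planned. Probe sets outside the named genes carried signal that no comparison above used. Of 1621 probe sets with several gene symbols, 114 passed adjusted p of 0.05 (limma), 78 higher and 36 lower in Geminin-KO, with log2 fold changes reaching 2.91 and -1.11. Of 5446 probe sets with no gene symbol in the annotation used, 224 passed, 124 higher and 100 lower, reaching 3.58 and -1.93. Each was compared with its level in the wild type arrays, and no gene is named for them.

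The splits of 6 arrays into 3 and 3 number 10, so the share of splits as large as the real one cannot go under 0.1. The real split gave 3194 genes past adjusted p of 0.05 and the highest other split 0, so 1 of 10 was as large. At unadjusted limma p of 0.05 the other splits gave 133 to 1224 genes, against 6174. For the thresholds stated for the study the real split gave 1764 and the highest other 148, again 1 of 10. For gene lists at the preset correlation, the 9 other splits gave 4 to 21 with 0 genes past adjusted p of 0.05. Each of them keeps part of the genotype difference and puts the rest within its groups, which raises the variance there. Their counts are therefore not a chance expectation, and cannot tell whether a high count of called lists marks a genotype effect. The count of called lists was 21 in 2 of 10 splits. These were the real one and the split of wild type replicates 1 and 2 with Geminin-KO replicate 3 against the other arrays. Whether a structure among the arrays or a preset correlation that is too small gives these counts was not tested. With an estimated correlation 0 lists passed.

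Stem cell genes rose while erythroid genes fell. If a lower share of erythroid cells had merely enriched every other cell type alike, markers of the other types would have shifted together. Among members above a mean log2 of 8.13, the stem cell list shifted by 1.15 (24 members) and the monocyte and macrophage list by 0.05 (13 members), a difference of 1.105 (SE 0.273). The monocyte list was chosen for this after its median was seen. It was uneven, at 0.14, -0.51 and 0.37 in the wild type arrays and 0.13, 0.37 and -0.37 in the Geminin-KO arrays. It also holds Slc40a1, a gene of erythroid cells too, whose fall lowers the list mean. The median log2 fold changes of the same members were 1.17 for the stem cell list and 0.155 for the monocyte list. The T and NK cell list shifted by 1.46 and the lymphoid list by 1.06. The latter was uneven, at 1.04, 2.02 and 0.12 in the Geminin-KO arrays against 0.64 in wild type replicate 3, while the stem cell list lay at 1.18, 1.14 and 1.14 in the Geminin-KO arrays. The median of all lymphoid members fell from 0.86 to 0.16 without Geminin-KO replicate 2. The mast cell, granulocyte and megakaryocyte lists shifted by 0.61, 0.55 and 0.50. Over the 7 lists other than erythroid, a permutation of 104 members gave p = 0.0054 for a shared mean. It took genes as independent replicates, though genes of a list can vary together across arrays, so it is not used as support. The difference between the stem cell and monocyte lists, whose SE is over arrays, argues against equal enrichment of all other types as the whole cause. It does not argue against an enrichment of several of them. A difference in scaling is argued against by the gap between the medians of the 2 lists, which was 1.73 on the deposited values and 1.592 under quantile normalization. A factor common to all genes of an array leaves that gap unchanged. A larger share of stem and progenitor cells among the sorted cells, and a change of expression within cells, both of which the genotype could bring about, remain open, since bulk RNA does not separate them.

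Of 12 mature neutrophil genes (Ltf, Ngp, Lcn2, Camp, Mmp8, Mmp9, S100a8, S100a9, Retnlg, Pglyrp1, Cxcr2 and Ly6g), chosen after the values were seen, Ltf and Ly6g rose, 10 were not called and 3 of these overlapped between groups. Ms4a3, also of the granulocyte list, fell by 1.67 (limma adjusted p = 0.0438). No member of that list fell past adjusted p of 0.05 without any one array other than wild type replicate 2. The early granule genes Elane and Ctsg had values of -1.80 (adjusted p = 0.0807) and -1.33 (adjusted p = 0.0532), neither of them called. Prtn3 and Mpo had values of -0.29 (adjusted p = 0.611) and -0.04 (adjusted p = 0.852). These 4 genes and Ms4a3 were named after their values were seen. The mean of the 12 genes lay at 0.33, -0.74 and 0.41 in the wild type arrays and 2.79, 2.03 and 0.77 in the Geminin-KO arrays, relative to the wild type mean. Their deviations from the group means went together, with a mean pairwise correlation of 0.837 across the 6 arrays. This was above all 1000 random sets of matched brightness (median -0.004). Mature neutrophils left in varying amounts would give such a correlation, though the sort against GR1 and CD11b should remove them. However, Elane, Ctsg, Prtn3, Mpo and Ms4a3 were also lowest within their groups in wild type replicate 2 and Geminin-KO replicate 3. The shared deviations were thus not particular to mature genes, and random sets do not control for a wider difference between arrays. Nor does a correlation within groups bear on the fall of Ms4a3. A gene program shared within progenitors may give the same correlation, so a change with genotype stays open, and S100a8 and S100a9 were among those that overlapped (log2 fold changes 1.26 and 1.63, adjusted p = 0.302 and 0.148).

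Interferon response genes rose. Geminin-KO replicate 2, the array without female signal, had the highest list mean, but without it the median was 0.626, with all 27 members positive and 13 past adjusted p of 0.05, so that array alone does not account for the rise. A strain segment carried along with the deleted gene could hold risen genes near it. By the RefSeq gene table of GRCm38.p6, 0 of the 14 risen members lie on chromosome 13, which holds Gmnn. A segment around Gmnn therefore does not hold these 14 genes. How many of all 27 members lie there was not counted, so the 0 does not show that risen genes avoid that chromosome. Of the 80 genes nearest Gmnn, 9 passed (11.2%, against 16% of all genes), so changed genes were not enriched there. An effect of a strain segment at Gmnn on genes elsewhere, and strain segments elsewhere in the mixed background, stay open. So do other cells in the sort and a response to the knockout. They were not tested apart.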

How the results depend on the processing

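Subtracting 16 before log2 was added after the data had been seen; the other alternatives were planned. The Gmnn log2 fold change stayed past adjusted p of 0.05 under each alternative run, and ran from -1.38 to -1.19 when 1 array was left out. Subtracting 16 kept 85 of 85 named calls and the 21 lists, and moved the Gmnn log2 fold change to -1.36. The count of 3194 genes ranged from 1535 to 3518 with 1 array left out, and the other alternatives except the block gave 2738 to 4749, the last at adjusted p under 0.1. At the stated thresholds, a fold over 2 in place of 1.5 left 694 of 1764 genes by its own construction, and the count was 1512 to 2072 with 1 array left out. The 21 lists became 0 with an estimated correlation, for a reason that was not tested, and 17 to 21 otherwise. Of named genes that were called, 81 of 85 or more kept the call under the scalings, priors and probe set choices run on them, and 63 to 84 of 85 with 1 array left out. The Kit log2 fold change turned to -0.045 without wild type replicate 1, with a range of -0.045 to 0.168 over the left-out arrays, and the Xist log2 fold change to 0.022 without Geminin-KO replicate 2, with a range of -2.72 to 0.022, the latter because that array alone lacked Xist. Neither was called, and the cause was not tested for Kit.

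With the replicate block, 1435 genes passed adjusted p of 0.05, of which 1398 were among the 3194, and 61 of 85 named genes kept their call. The stated thresholds gave 1708 and the lists 21. The numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.037, -0.421 and -0.301 across genes, and no array correlated best with its own number in the other genotype. The block uses 2 degrees of freedom. The table gave no measure of signal over background, so folds of dim genes, such as the mast cell proteases in wild type, were not checked against it.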

Other observations

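The observations in this part, the gene families and the test of mixed sexes included, were chosen after the data had been seen. Genes were grouped by all letters of their symbols before the first other character, so that Cdk genes, for example, are not in the Cd group. The 674 tests (groups of at least 8 genes, each for rises and for falls, one-sided Fisher's exact test) gave 14 past adjusted p of 0.05. Genes in a group are not independent, so these p-values only rank the groups. The clearest group was the Gimap family, small GTPases of lymphocytes, of which 8 of 8 rose (adjusted p = 6.71e-06, median log2 fold change 1.34), and 7 or 8 did so whichever array was left out. Gimap6 rose from 9.02 ± 0.658 to 11.63 ± 0.153 (log2, SD, n = 3; log2 fold change 2.60, SE 0.311, adjusted p = 0.00407), Gimap4 by 2.17 (SE 0.347) and Gimap5 by 2.02 (SE 0.221). Quantile normalization and median centring left the median at 1.29 and 1.30. Other lymphocyte genes were higher in the same arrays, with T and NK cell list means of 0.78, 1.14 and 0.46 in Geminin-KO and Cd3g at 1.61. So were the general leukocyte gene Ptprc, at 1.63, and stem cell genes, with list means of 1.07, 1.03 and 1.03. The Gimap rise was not tested apart from any of these.

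Ahead of or among the families described below, 28 of 94 genes of the Cd group (adjusted p = 2.62e-05) and 7 of 10 Hoxa genes (adjusted p = 0.00154) rose. In the Slc group, 41 of 364 genes fell (adjusted p = 0.00691) while 52 rose. The Sh, Camk, Map, Il, Arhgap and Oas groups also passed for rises (Fisher's exact test, adjusted p = 0.00536 to 0.043) and are not described further. The Cd count was 12 to 18 and the Slc count 21 to 24 without wild type replicate 1 or 2 or Geminin-KO replicate 1 or 2. Of 16 genes whose symbols open with Pik, mostly subunits of phosphoinositide 3-kinases, 9 rose (adjusted p = 0.00133), with Pik3cg at 1.09 (SE 0.17), Pik3cd at 0.99 (SE 0.148) and Pik3r1 at 0.40 (SE 0.082), while Pik3r2 fell by 0.68 (SE 0.154). Of 8 Smad genes, which carry signals of the TGF-beta and BMP families, 6 rose (adjusted p = 0.00316), led by Smad5 (log2 fold change 0.91, SE 0.075, adjusted p = 0.00162) and Smad7 (0.83, SE 0.163). Of 20 TNF receptor superfamily genes, 9 rose (adjusted p = 0.00574) and Tnfrsf14 fell by 0.73 (SE 0.064). In the other direction, 7 of 20 Snora genes, which encode small nucleolar RNAs, fell (adjusted p = 0.00806), with Snora73b at -0.98 (SE 0.192). Without Geminin-KO replicate 1, 3 Pik, 3 Smad and 5 TNF receptor genes rose and 1 Snora gene fell. Without wild type replicate 1 these counts were 3, 4, 7 and 2, without wild type replicate 2 they were 4, 4, 7 and 3, and without Geminin-KO replicate 2 they were 4, 5, 6 and 2. Medians of these families kept their sign under both other scalings.

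Xist and Y-linked transcripts were seen in the same arrays. In 5 of the 6 arrays Xist and Eif2s3y both lay above the median of all genes, as RNA pooled from embryos of both sexes would give. Background or cross-hybridization of the Y-linked probe set in female samples was not tested and is not excluded. Eif2s3y was at 9.95, 8.65 and 8.82 in the wild type arrays and 9.64, 10.26 and 9.43 in Geminin-KO, and the array without a high Xist, Geminin-KO replicate 2 at 6.93, had the highest Eif2s3y. A candidate explanation is that most samples pooled embryos of both sexes in differing shares and that replicate came from males. The labels used here do not say how many embryos a sample held.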
